A study of Homo sapiens with 6 samples.

How the data were processed

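RNA sequencing gave 6 libraries of SH-SY5Y, a human neuroblastoma line. Per the labels' protocols, the cells had been differentiated with retinoic acid, made insulin resistant (IR) over 24 h in D-glucose at 30 mM plus insulin at 100 nM, and either left at that (IR control, 3 libraries) or given Oligonol at 500 ng/mL for 24 h (IR+Oligonol, 3 libraries). Libraries were made from total RNA with a stranded total RNA kit and read on both ends for 100 nt, per the labels' protocols. The submitters' processing notes name FastQC, kallisto 0.46.1, edgeR and the genome build GRCh38.p13, with no role or order. How transcript estimates became gene values is not given in the sources used here.

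The deposited table lists 61860 genes with GRCh38.p13 coordinates and, for each library, a column of estimated counts and a column of a scaled signal. The authors deposited both columns side by side. Within a library, the deposited signal was the estimated count times 1 constant, so the signal added no information. The deposited estimated counts were not whole numbers (99.0 to 99.1% of values above 0) and behaved as transcript abundances scaled to a library total. For low genes with 1 annotated transcript of 500 to 1500 nt, values were multiplied by effective transcript length and divided by a scale. Of these values 79.2 to 82.1% then lay within 0.05 of a whole number of reads. Fragment length and scale were fitted in each library to favour whole numbers, so that share is no independent check. On that scale 1 read of a 1000 nt transcript was worth 0.312 to 0.549 estimated counts, and 1 read of an RNA of 80 to 99 nt was worth 17.7 to 37.6. Short RNAs therefore weigh far more in these totals than their reads. An RNA under 100 nt with 200 estimated counts rests on a few reads, and counting noise is understated for it and overstated for long mRNAs. Protein-coding genes rested on 5170095 to 6405122 read equivalents per library. For 153 genes with a total over 100, the values in all 6 libraries were identical to those of another gene. Whether such genes share sequence was not checked, and they are reported as uncertain.

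Of the gene identifiers, 58308 were matched to GENCODE release 29, which gave biotype, transcript length and transcript GC content (medians over a gene's transcripts). Its release need not be the one the authors used. Start and end were the same for 41719 identifiers, and coordinates are given as the deposited table has them.

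Estimated counts were rounded. Genes were kept by filterByExpr with the groups (16574 genes), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust, group as the only term, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Group levels are CPM after TMM scaling, mean ± SD, n = 3, and fold changes are log2 with the standard error (SE) implied by the test. The 39 gene lists (1221 of 1222 entries matched a gene) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for the 36 lists with at least 5 tested members. Members were also adjusted over the list alone. The composition of libraries was compared with an exact 2-sided permutation test, which cannot go below p = 0.1 with 3 against 3. Whether the 3 replicates of a group came from separate cultures is not given in the sources used here, so p-values measure the spread between these samples, which may be technical.

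The design, tests, lists and naming rule were fixed before the data were examined. The rule named, among genes with a symbol, a mean log2 CPM of at least 1, an adjusted p under 0.05 and groups that did not overlap, the 10 largest rises and 10 largest falls. It also named the 2 members of each list with the smallest p, up to 4 in lists called by the set test, and 14 fixed genes (INSR, IRS1, IRS2, BDNF, APP, BACE1, MAPT, SYP, DLG4, HMOX1, NQO1, TXNIP, IL6 and TNF). Some genes that the rule named are not reported here. Because the first part returned mostly RNAs under 200 nt, protein-coding genes meeting the same conditions were added after the values were seen, as were those called both with and without the GC trend. 5.8S and 5S rRNA, olfactory receptor genes and biotypes were also singled out after their values were seen.

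After a trend with GC content was seen, each library's trend was removed as an added alternative: a natural spline (5 degrees of freedom) of log2 CPM, less the gene's mean, on transcript GC, fitted on protein-coding genes and entered as an offset. It could be applied to 16200 tested genes (97.7%). This removes any true change that follows GC along with a technical one. Alternatives chosen beforehand were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma-voom, no filter, a filter of at least 10 counts in all libraries, genes with a symbol, the replicate number as a block, each library left out, other thresholds, and camera with an estimated correlation and fry. Added ones were length trends, read equivalents, limma on the log2 of the deposited signal with a pseudocount of 1 or 0.1, protein-coding genes, and transcripts of at least 200 nt. Tables were handled with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.

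The tests were checked on simulated counts of the same libraries with 200 changed genes. Without a GC trend, 6.06% of 1.5-fold, 38.8% of 2-fold and 97.0% of 4-fold changes were recovered, and 3 of 15158 unchanged genes were called. With a GC trend between the groups and no GC term, 4030 of 15735 unchanged genes were called. With the trend removed, 5 of 15412 were called, and recovery was 0 of 62 at 1.5-fold, 21.5% at 2-fold and 89.6% at 4-fold. The simulated trend was a straight line in the same GC values, equal in all libraries of a group. Real trends also differed within a group, with a rho of -0.761 between GC and the log ratio of Oligonol libraries 1 and 2. The simulated rates therefore need not hold for the real libraries.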

Results

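Gene expression was measured in retinoic acid-differentiated SH-SY5Y cells, a neuron-like human neuroblastoma line, made insulin resistant with high insulin and high glucose. The comparison asks how Oligonol, a polyphenol preparation derived from lychee fruit, altered the transcriptome of such cells. It set 3 IR+Oligonol libraries against 3 IR control libraries, and cells without induced insulin resistance were not analysed here. Estimated counts summed to 22738203, 25328857 and 32209583 in the control libraries and to 19457923, 20912945 and 20100206 in the Oligonol libraries.

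The Oligonol libraries differed from the controls in composition. The abundant small RNAs RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP, parts of the signal recognition particle, a transcription regulator and RNA-processing enzymes, held 74.8% ± 2.29 (SD, n = 3) of estimated counts in controls and 60.9% ± 3.15 with Oligonol. Protein-coding genes held 6.60% ± 0.313 and 11.4% ± 1.22, and the mitochondrial rRNAs 4.05% ± 0.540 and 8.65% ± 2.10. The 10 most abundant genes took 80.5% ± 2.11 and 71.7% ± 1.29, mitochondrially encoded mRNAs 0.410% ± 0.0918 and 0.866% ± 0.165, cytosolic ribosomal protein genes 0.863% ± 0.0632 and 1.26% ± 0.0564, and nuclear-retained long non-coding RNAs 0.0105% ± 0.00233 and 0.0574% ± 0.0199. In each of these measures every Oligonol library lay outside the range of the controls, with exact 2-sided permutation p = 0.1, the smallest that 3 against 3 can give, as for the library totals. Replication-dependent histones held 0.849% ± 0.0963 of all counts in controls and 0.823% ± 0.0311 with Oligonol (exact permutation p = 0.6). As a share of protein-coding counts they held 12.9% ± 2.02 and 7.27% ± 0.604 (exact permutation p = 0.1), ribosomal protein genes 13.1% ± 1.30 and 11.2% ± 1.74 (exact permutation p = 0.2), and mitochondrially encoded mRNAs 6.185% ± 1.139 and 7.585% ± 0.9878 (exact permutation p = 0.3), with overlapping groups for the last 2. Nuclear-retained long non-coding RNAs amounted to 0.158% ± 0.0286 and 0.496% ± 0.131 of protein-coding counts (exact permutation p = 0.1). Shares of protein-coding counts, the shares of the small RNAs, of protein-coding genes and of mitochondrial rRNAs, and GC content were measures added after the values were seen. The median GC content of protein-coding counts was 56.1% ± 0.174 in controls and 52.3% ± 1.61 with Oligonol (exact permutation p = 0.1), and Oligonol library 2 (54.1%) lay between the controls and the other Oligonol libraries (51.2 and 51.6%).

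**Figure D1:**
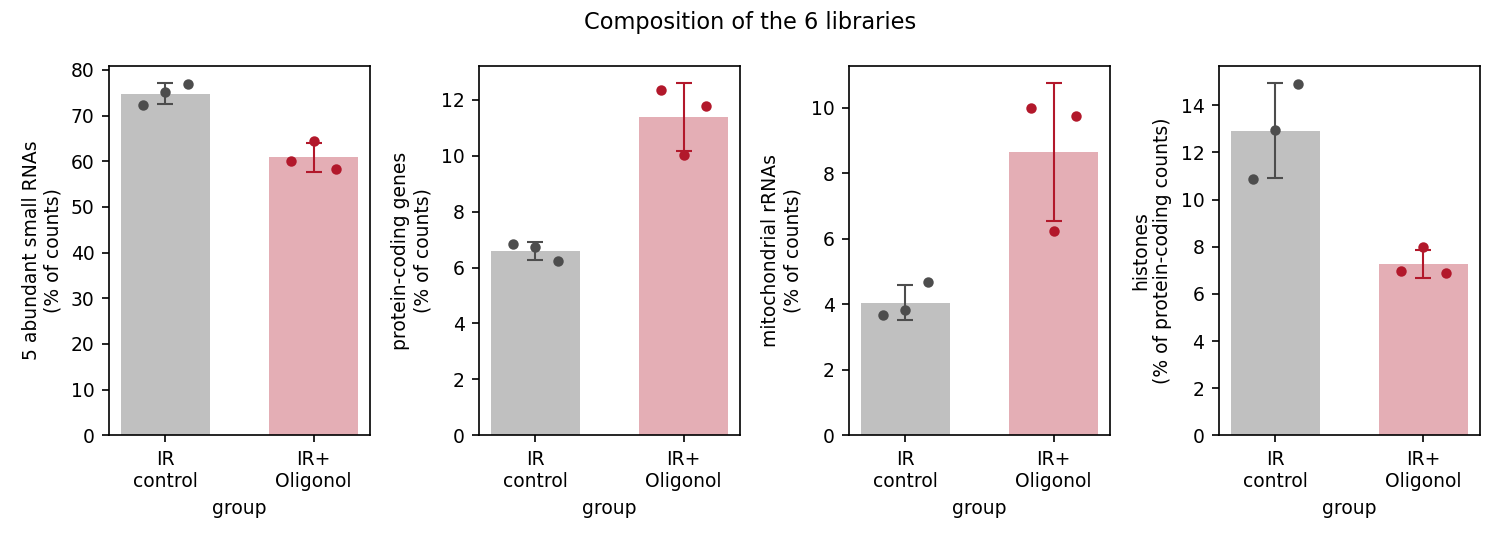
Composition of the 6 libraries by group: bars are means, error bars 1 SD, points the 3 libraries of a group, and the vertical axes percent of estimated counts (last panel, percent of protein-coding counts). The share of 5 abundant small RNAs was 74.8% in controls and 60.9% with Oligonol, and that of protein-coding genes 6.60 and 11.4%.

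Among 16574 tested genes, 4304 were higher and 3808 lower with Oligonol by edgeR's quasi-likelihood test at an adjusted p under 0.05. Without Oligonol 1 it called 2225 higher and 1459 lower, and without Oligonol 3 2118 and 1321. Among protein-coding genes, direction followed GC content: in the lowest of 10 equal bins of GC (32.0 to 40.3%), 879 of 1172 were higher and 1 lower, and in the highest (62.4 to 74.2%), 2 were higher and 951 lower. Across 11719 protein-coding genes, which are not independent replicates, Spearman's rho of log2 fold change with transcript GC was -0.851. With each library's GC trend removed, an alternative added after this was seen, 466 genes were higher and 416 lower, of which 685 had been called in the same direction before. No gene was called with the GC trend removed when control 2 or Oligonol 3 was left out, while 3444 and 3052 genes had an unadjusted p under 0.05 in those fits. Scaled by library totals alone, 11293 genes were higher and 37 lower, with a median log2 fold change of 1.53 against 0.15 under TMM, so all directions here are relative to TMM scaling.

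**Figure D2:**
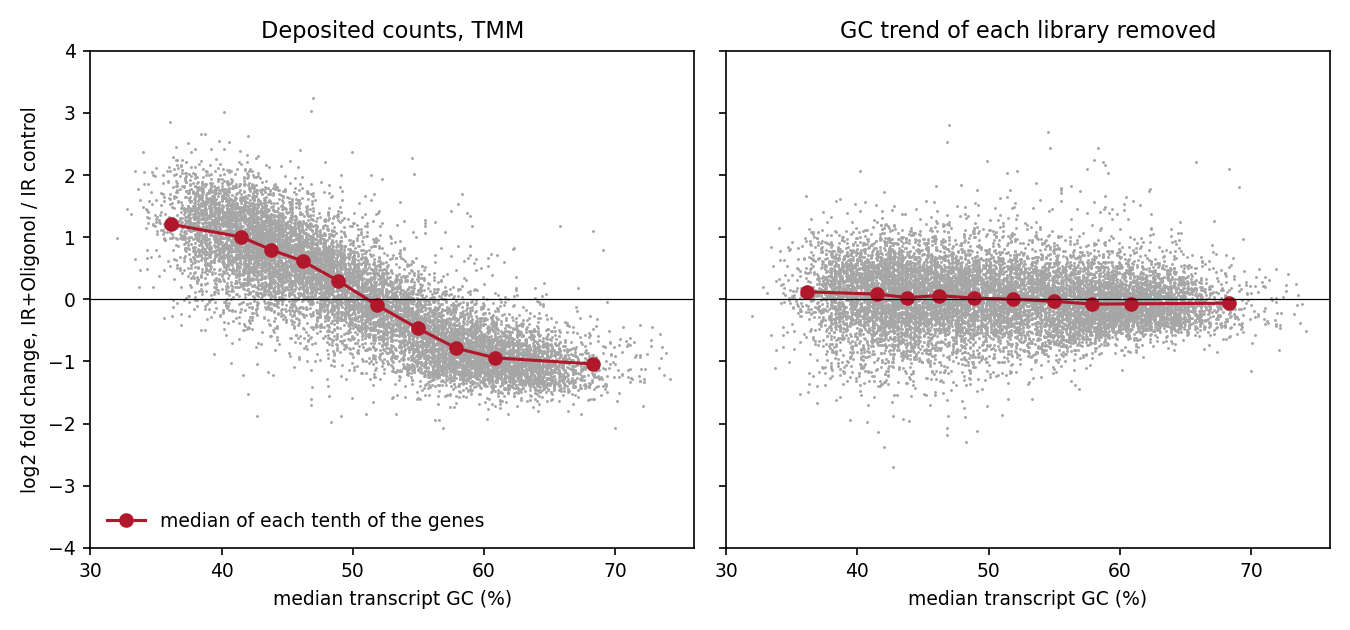
Log2 fold change (vertical) of protein-coding genes against median transcript GC in percent (horizontal), before and after each library's GC trend was removed. Grey points are genes, and red points medians of 10 equal bins of genes, which ran from 1.21 to -1.04 before removal and from 0.12 to -0.06 after.

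By the fixed rule, all 10 of the largest rises had transcripts under 200 nt and were listed at 0 in every control library, including MIR15B, MIR548E, MIR1305, RNA5SP118 and SNORD111B. MIR548E was 3.78 ± 0.634 CPM with Oligonol, which came to at most 4.32 reads in a library. SNORA50A, a snoRNA, is listed under 2 gene identifiers at 1 place (GRCh38.p13 chromosome 16, from 58559796). One was at 10.6 ± 1.94 CPM in controls and 0 in all Oligonol libraries, and the other at 0 in all controls and 4.69 ± 1.83 CPM with Oligonol, so the locus itself cannot be read as risen or fallen. Of the 10 largest falls 7 were RNAs under 200 nt, including SNORA6 (log2 fold change -1.98, SE 0.20) and SNORD15A (-1.99, SE 0.25), and the others were RMRP, the histone gene H2AC18 (937.2 ± 269.1 to 210.7 ± 52.12 CPM) and CRYGC. RMRP, the RNA of the RNase MRP enzyme, is also listed under 2 overlapping identifiers (chromosome 9, from 35657751 and from 35657754). The less abundant fell from 5592 ± 994.9 to 1353 ± 267.4 CPM (-2.05, SE 0.29, adjusted p = 0.00620) and the other from 38060 ± 5477 to 13510 ± 4679 (-1.49, SE 0.33, adjusted p = 0.0115). After removal of the GC trend they stood at -1.08 (adjusted p = 0.0490) and -0.55 (adjusted p = 0.213).

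The 10 largest rises of protein-coding genes were chosen by the same conditions after the values were seen. They were MAGI2, SYT14, DNAJC13, PDS5B, MYEF2, IL6ST, CNTNAP2, C2CD5, PGAP1 and VPS13A. DNAJC13 had the smallest p of these (log2 fold change 2.54, and 1.56 with the GC trend removed). CNTNAP2, a neurexin-family adhesion protein of axons (chromosome 7, 146116002 to 148420998), went from 1.15 ± 0.606 to 6.11 ± 0.753 CPM (log2 fold change 2.40, SE 0.32, adjusted p = 0.00615). MAGI2, a scaffold of synapses, had a log2 fold change of 3.03 (SE 0.56), SYT14, a synaptotagmin, 2.85 (SE 0.39), and IL6ST, the shared receptor subunit gp130, 2.41 (SE 0.33). With the GC trend removed the values were 1.83 for CNTNAP2, 2.54 for MAGI2, 1.67 for SYT14 and 1.43 for IL6ST, and MAGI2 no longer passed (adjusted p = 0.0566). CNTNAP2 and MAGI2 are long genes, and across protein-coding genes the fold change with the GC trend removed rose with genomic span (Spearman's rho 0.365). The largest falls were CRYGC, a lens crystallin (-2.07, SE 0.27), MTLN, a mitochondrial micropeptide (-1.95, SE 0.31), the cytochrome c oxidase assembly gene SCO2 (-1.79, SE 0.28) and histone genes. Without the GC trend CRYGC stood at -1.45, MTLN at -1.37 and SCO2 at -0.80, all past the threshold.

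Replication-dependent histones, which package newly made DNA, were the most uniform group: 34 of 37 tested members fell and none rose (34 and 0 when adjusted over the list alone). H3C8 (chromosome 6, 26270918 to 26271413) fell from 414.8 ± 82.9 to 112.7 ± 23.1 CPM (-1.88, SE 0.29), and H3C10, H4C9 and H4C12 had log2 fold changes of -1.885, -1.70 and -1.79. The list's median was -1.43 and camera gave an adjusted p of 1.07e-11, against an adjusted p = 0.787 with an estimated correlation. Histone copies are near identical, so single members are uncertain. With the GC trend removed the median was -0.84, and 8 of 35 members passed (25 over the list alone). H3C8 then stood at -2.70, H3C10 at -2.11, H4C9 at -2.18 and H4C12, no longer past the threshold, at -0.81 (adjusted p = 0.0660). H3C8 and H4C9 drew their GC (42.7 and 46.8%) from transcripts of 2411 and 1294 nt, longer than the deposited genes. H3C10 (49.1%) and H4C12 (64.1%) did not. The deeper falls of H3C8 and H4C9 without the GC trend are therefore less sure.

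Cytosolic ribosomal proteins fell in 20 of 78 cases, with no rise and none past the threshold when adjusted over the list alone. RPL10 went from 467.6 ± 90.6 to 181.6 ± 64.0 CPM and RPL13A from 367.1 ± 69.4 to 154.8 ± 55.1. Nuclear-encoded oxidative phosphorylation genes fell in 14 of 47 cases and rose in 1 (10 and 1 over the list alone): CYC1 of complex III had a log2 fold change of -1.42 (SE 0.31), NDUFS8 and NDUFA2 of complex I -1.25 each, and UQCRC2 1.20. Camera gave adjusted p = 2.08e-05 and 0.0322 for these lists, and adjusted p = 0.787 for both with an estimated correlation. With the GC trend removed, medians were -0.61 for ribosomal proteins, with no member past the threshold, and -0.50 for oxidative phosphorylation, with 9 of 47 lower (24 lower and 1 higher over the list alone), among them NDUFA2 (-1.18) but not CYC1 (-0.50) or NDUFS8 (-0.31). Mitochondrially encoded mRNAs had no member past the threshold by the planned test (list median -0.10). Camera on values without the GC trend called them lower (median -0.82, adjusted p = 6.73e-06, 1 of 13 past the threshold and 9 over the list alone), and not with an estimated correlation (adjusted p = 0.776).

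mRNA splicing factors rose in 22 of 40 cases and fell in 2 (24 and 3 over the list alone), among them PTBP2, a neuronal splicing repressor (log2 fold change 2.03, SE 0.32), MBNL2 (1.58, SE 0.28) and the branch-point factor SF3B1 (1.33, SE 0.22). Immediate early genes fell in 6 of 26 cases and rose in 1 (5 and 1 over the list alone): JUNB had -1.38 (SE 0.30), DUSP2 -1.37, JUN -0.66 and KLF10 0.94. Genes of glucose uptake and glycolysis fell in 10 of 25 cases and rose in 3 (11 and 4 over the list alone), with LDHA, which makes lactate, at 1.30 (SE 0.21) and the phosphofructokinase genes PFKL and PFKFB4 at -1.07 and -0.9955. Camera gave adjusted p = 0.00974, 0.0324 and 0.0344, and adjusted p = 0.787 for each with an estimated correlation. The median GC of these lists was 44.8, 56.9 and 55.8%. With the GC trend removed their medians were 0.04, 0.19 and -0.11, with adjusted p of 0.964, 0.197 and 0.400, and no member passed over all genes. PTBP2 stood at 0.89, JUNB at -0.39 and LDHA at 0.68. Of the 9 splits of the 6 libraries that mix the groups, 1 also gave 6 called lists, so the number of called lists does not set the real grouping apart.

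**Figure D3:**
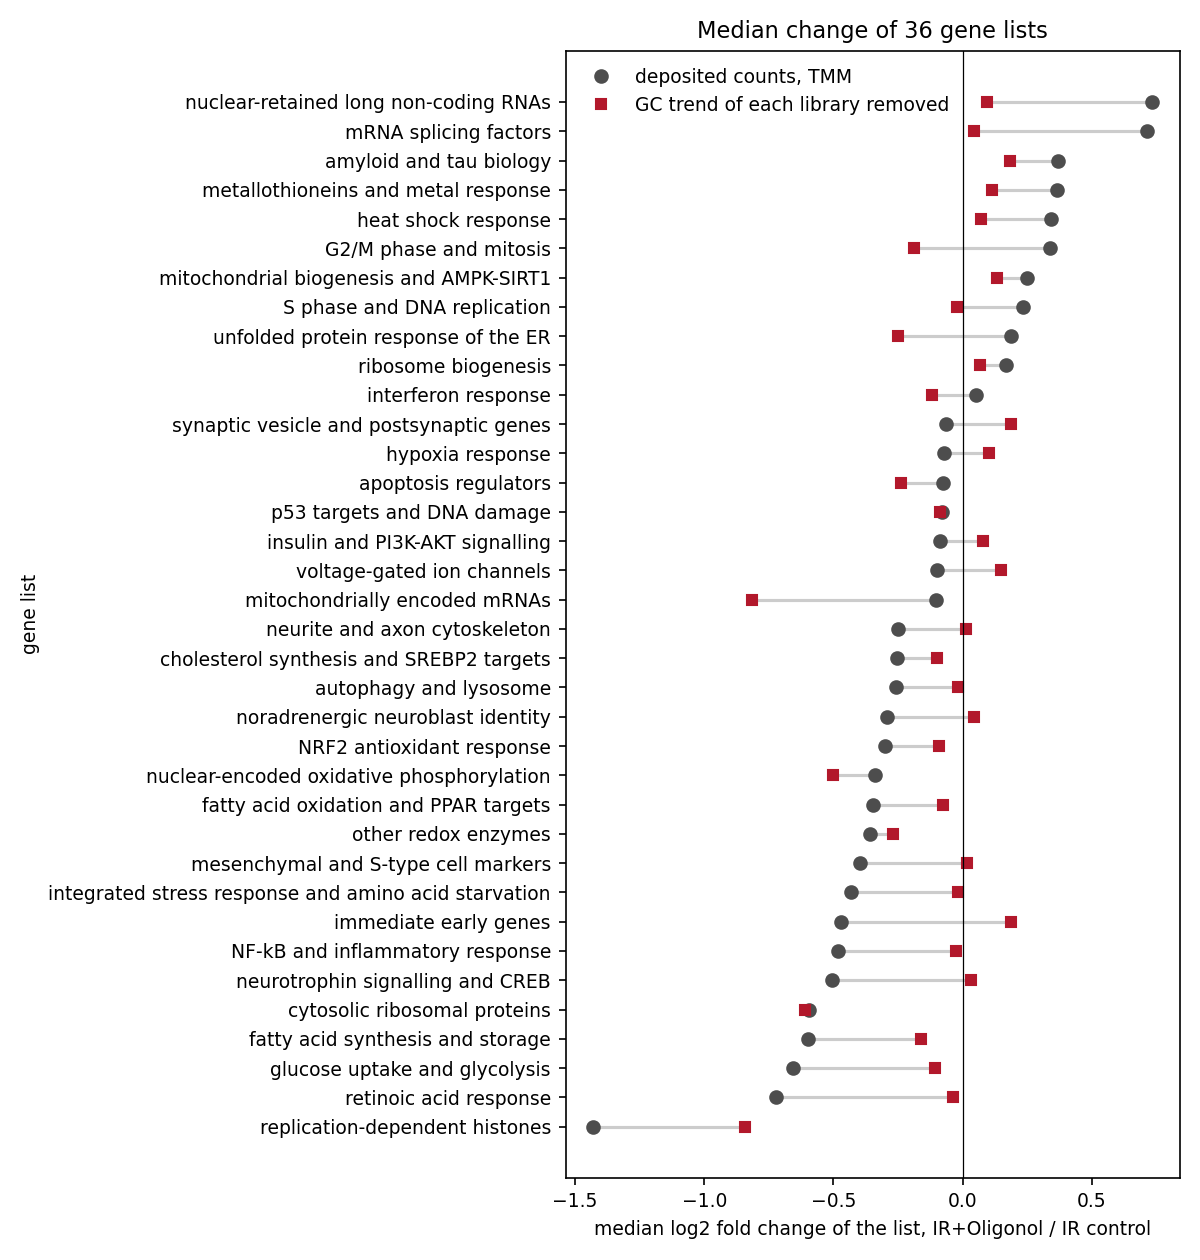
Median log2 fold change of the tested members of 36 gene lists (horizontal), from the deposited counts (grey circles) and with each library's GC trend removed (red squares). Replication-dependent histones lay at -1.43 and -0.84, and mRNA splicing factors at 0.71 and 0.04.

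The other 30 lists were not called by camera with the planned fit. In insulin and PI3K-AKT signalling, 10 of 31 genes rose and 11 fell (0 and 1 without the GC trend). INSR, the insulin receptor, was 2.15 ± 0.487 CPM in controls and 1.89 ± 0.504 with Oligonol (adjusted p = 0.594), and IRS2, its adaptor, 2.69 ± 0.735 and 2.54 ± 0.0821 (adjusted p = 0.763). Their log2 fold changes of -0.18 and -0.09 became 0.28 (adjusted p = 0.572) and 0.69 (adjusted p = 0.129) without the GC trend. TXNIP, a glucose-induced inhibitor of thioredoxin, rose from 1.81 ± 0.277 to 3.38 ± 0.531 CPM (0.90, SE 0.21, adjusted p = 0.0126). Without the GC trend it stood at 0.36 (adjusted p = 0.293).

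In amyloid and tau biology 11 of 32 genes rose and 9 fell (0 and 0 without the GC trend, 5 and 6 over the list alone). APP, the amyloid precursor, rose from 10.2 ± 1.55 to 16.2 ± 1.53 CPM (0.67, SE 0.20, adjusted p = 0.0277) and stood at 0.39 (adjusted p = 0.195) without the GC trend. BACE1, which cleaves APP, was 5.41 ± 1.14 and 4.49 ± 0.430 CPM (adjusted p = 0.286), and MAPT, encoding tau, 2.87 ± 0.383 and 2.15 ± 0.0953 CPM (adjusted p = 0.0824). Without the GC trend BACE1 turned from -0.27 to 0.15 (adjusted p = 0.620) and MAPT from -0.42 to 0.29 (adjusted p = 0.304). Of 40 synaptic genes 13 rose and 11 fell (1 and 0 without the GC trend). SYP, encoding synaptophysin, fell from 16.7 ± 2.15 to 6.47 ± 1.98 CPM (-1.37, SE 0.26) and DLG4, encoding PSD-95, from 4.83 ± 0.268 to 2.84 ± 0.608 (-0.77, SE 0.20). Without the GC trend they stood at -0.60 and -0.04, neither past the threshold, and by library totals alone DLG4 was higher (0.58).

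In the NRF2 antioxidant response 4 of 25 genes rose and 7 fell (0 and 2 without the GC trend). NFE2L2, encoding NRF2 itself, had a log2 fold change of 1.03 (SE 0.19), the carbonyl reductase CBR1 -1.32 (SE 0.18), and NQO1 3.98 ± 0.926 against 2.80 ± 0.302 CPM (adjusted p = 0.0765). CBR1 passed also without the GC trend (-0.78, adjusted p = 0.0408), while NFE2L2 stood at 0.28 and NQO1 at -0.84 (adjusted p = 0.0514). In the NF-kB and inflammatory response 3 of 21 rose and 8 fell (0 and 1 without the GC trend), with the inhibitor NFKBIA at -0.79 (SE 0.18) and at -0.30 without the GC trend. Too few counts for testing were found for IRS1, BDNF, HMOX1, IL6 and TNF. BDNF had 0.527 ± 0.194 estimated counts in controls and 2.13 ± 0.175 with Oligonol, IRS1 4.32 ± 0.922 and 11.02 ± 5.57, HMOX1 10.4 ± 1.79 and 12.2 ± 3.53, IL6 0.0900 ± 0.156 and 0.370 ± 0.242, and TNF 0.350 ± 0.303 and 1.01 ± 1.52, none scaled for library composition.

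Markers of cell identity were mixed. Of 19 noradrenergic neuroblast genes 3 rose and 3 fell (1 and 0 without the GC trend), with TBX2 at -1.10 and HAND1 at -0.77 (-0.08 and -0.13 without the GC trend). Of 20 mesenchymal genes 2 rose and 6 fell (0 and 1), with CALD1 at 1.45 and TAGLN at -1.34 (0.94 and -0.61, neither past the threshold). Of the glial markers 4 were tested, with 1 higher and 1 lower, and of the myeloid markers CD68 alone was tested and did not pass. Of 15 retinoic acid response genes 2 rose and 8 fell (1 and 1), with the receptors RARB at 0.96 (SE 0.19) and RARG at -1.10 (SE 0.24), and at 0.36 and -0.20 without the GC trend.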

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

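The test of the sum of receptor values, that of receptors with counts in both groups and that of gene span were chosen after the results were seen. Olfactory receptor genes, which neurons outside the nose are known to leave almost silent, had a signal although 376 of 381 lay outside the tested set. The deposited signal summed over those 376 was 3.69, 2.50 and 1.81 in the control libraries and 10.5, 5.43 and 10.8 in the Oligonol libraries, a mean 3.35 times that of controls, and all 3 Oligonol libraries lay above every control. The planned test, on the median receptor gene, decided nothing, because that gene was at 0 in all 6 libraries. Over all 381, the log2 ratio of the sums was 1.674 (SE 0.401), against a median of 0.76 for tested protein-coding genes of like GC, but receptors at the floor of detection do not exclude the GC trend. The 113 receptors with counts in both groups had a median log2 ratio of 1.644, above that 0.76 and the 0.49 of long intergenic RNAs. Processed pseudogenes came closer, with a median of 1.096. All these comparison medians are of tested genes, which most receptors were not, so the sets differ in level. The 95% bootstrap interval of the receptors' median (1.409 to 1.871) resampled genes and not libraries, so it leaves out the spread between libraries. More unspliced or genomic sequence in the Oligonol libraries is a candidate explanation. Across protein-coding genes, the fold change with the GC trend removed rose with genomic span (Spearman's rho 0.365). That explanation does not require such a rise, since the deposited values derive from transcript estimates, so the rise does not decide it. A change in the transcription of long genes caused by Oligonol was not tested apart from unspliced or genomic sequence and stays open.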

How the results depend on the processing

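Alternatives with the GC trend removed, read equivalents, the deposited signal, length and gene subsets were chosen after the data were seen. The count of changed genes stayed within 1.5 times of 8112 with RLE, upper-quartile and library-total scaling, DESeq2 and limma-voom. It was 4567 with no filter on low counts, and 3439 to 8921 with 1 library left out (3684 without Oligonol 1, 3439 without Oligonol 3). With the GC trend removed it was 882, with the longest transcript's GC 1443, with GC and length 1164, and for read equivalents 1793. Replicate numbers gave no sign of pairing the samples (same-number correlations 0.161, -0.153 and -0.226, and not every library correlated best with its own number). Differences along GC within a group enter these correlations and could hide a pairing, so pairing is not excluded. With the replicate number as a block there were 7030 genes and 6 lists, and 0 genes with the block and the GC trend removed (3986 at an unadjusted p under 0.05). With the GC trend removed and 1 library left out, counts were 1306, 0 and 51 without controls 1, 2 and 3, and 2, 623 and 0 without Oligonol 1, 2 and 3.

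Called lists went from 6 to 2 with library totals, 16 with no filter, and 3 with named genes, protein-coding genes, or limma on the signal with either pseudocount. With at least 10 counts in all 6 libraries 4 were called, 2 higher and 2 lower, against 1 and 5 in the planned fit. With 1 library left out 3 to 6 were called (3 without control 3 or Oligonol 1). With an estimated correlation 0 lists were called, with or without the GC trend, while fry called 7 in 1 direction and 34 as mixed. Those 7 were largely other lists than camera's. They held histones (fry adjusted p = 0.0484) and splicing factors (0.0302). They did not hold ribosomal proteins (0.174), oxidative phosphorylation (0.169), immediate early genes (0.0689) or glucose uptake and glycolysis (0.0917). Histones were called lower in all 33 other fits with the preset correlation, and ribosomal proteins in all but library totals.

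Medians below are relative to all tested genes. With library totals the camera test of immediate early genes turned in sign alone (adjusted p = 0.993). Their median stayed at -0.625, against -0.618 in the planned fit. The set test also turned at 0.155 with the GC trend removed and, with a median still negative, at -0.024 with the longest transcript's GC. Medians were 0.112 with GC and length, 0.142 with GC and block, and 0.163 for read equivalents without the GC trend. Leaving out controls 1, 2 or 3 as well gave 0.116, 0.116 and 0.208, and leaving out Oligonol 1, 2 or 3 gave 0.110, 0.161 and 0.167. Splicing factors turned at -0.044 with the longest transcript's GC, -0.019 with GC and length, -0.024 for read equivalents without the GC trend, and, with the GC trend removed, -0.020 without control 3 and -0.030 without Oligonol 2. The difference in the histone share of all counts ranged from -0.0782 to 0.01605 percentage points with 1 library left out, turning positive without control 3.

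Scaling by library totals raises all fold changes by construction, and these named genes turned higher (log2): H2BC9 0.179, ATP5MG 0.217, H2BC7 0.363, RPL13A 0.087, RPS15 0.142, RPL18 0.097, NDUFS8 0.089, NDUFA2 0.114, JUN 0.728, PFKFB4 0.385, PFKL 0.238, RARG 0.253, AGPAT2 0.048, TBX2 0.265, HAND1 0.570, CPT1C 0.177, CPT1B 0.276, TNFAIP2 0.008, NFKBIA 0.609, SESN2 0.277, MVK 0.052, CBR1 0.059, CASP9 0.265, CACNB1 0.266, BOP1 0.092, IRF7 0.215, SYVN1 0.336 and DLG4 0.584. With the length trend removed SNORA15B-1 and SNORA15B-2 (0.309 each), SNORD15A (0.282) and SNORA6 (0.196) turned, which are short RNAs far from the lengths the trend was fitted on. With GC trends removed JUN turned to 0.010 (longest transcript), 0.001 (without control 3) and 0.039 (without Oligonol 2), NORAD to -0.057 (without Oligonol 2) and DLG4 to 0.019 (without Oligonol 3). INSR, IRS2, BACE1 and MAPT, called in neither fit, turned to 0.279, 0.688, 0.151 and 0.294 with the GC trend removed. Other causes were not tested. Of 134 named genes, 78 lost their call with the GC trend removed and kept their direction. Tests per transcript and the pseudocount and filter choices planned for a file without counts were not run, since the table holds estimated counts per gene.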

Other observations

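After TMM scaling, 5.8S and 5S rRNA were higher with Oligonol, against the GC trend. The 2 mitochondrial rRNAs were not called (median log2 fold change -0.273). The cause was not tested. The 5.8S rRNA gene RNA5-8SN3 went from 34.45 ± 16.83 to 410.7 ± 196.1 CPM (log2 fold change 3.58, SE 0.53, and 4.199 without the GC trend) and the 5S gene RNA5S1 from 3.38 ± 2.17 to 27.8 ± 14.2 (3.03, SE 0.61). All 22 tested 5.8S and 5S copies with such names were called higher, but all except RNA5S9 hold values identical to the other copies of their family, so single copies are uncertain. Among 306 snoRNAs, guides of rRNA modification, 23 were higher and 91 lower (11 and 57 without the GC trend), and of 333 processed pseudogenes 122 were higher and 5 lower (22 and 0). Of 1526 tested genes with transcripts under 200 nt, 356 were called, and 143 of these were listed at 0 in all 3 controls against 4 at 0 in all Oligonol libraries.

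Other fixed lists moved both ways. Each gene below has 2 log2 fold changes, the first from the deposited counts and the second with the GC trend removed, where POLA1, CANX and DDX58 alone of them passed the threshold. Cholesterol synthesis genes rose in 7 and fell in 11 of 28 cases, with MVK, mevalonate kinase, at -1.30 and -0.44. Fatty acid synthesis genes rose in 1 and fell in 10 of 21 (FASN -1.41 and -0.42), fatty acid oxidation genes rose in 4 and fell in 8 of 23 (CPT1C -1.16 and -0.34), and heat shock genes rose in 9 and fell in 3 of 21 (HSPH1 1.53 and 0.535, HSPD1 1.14 and 0.47). Of S phase genes 12 of 36 rose and 6 fell (POLA1 2.04 and 1.19), and of nuclear-retained long non-coding RNAs 7 of 12 rose and 1 fell (TUG1 1.37 and 0.47, NORAD 1.04 and 0.13). In the mitochondrial biogenesis list 5 of 18 rose and 4 fell (PRKAA1 1.56 and 0.66, SIRT1 1.46 and 0.40). Among interferon genes 5 of 19 rose and 7 fell: DDX58, the RNA sensor RIG-I, went from 0.0609 ± 0.00333 to 0.526 ± 0.0712 CPM (3.02 and 2.06), and IRF7 stood at -1.13 and -0.12. Control values of DDX58 (0.0584 to 0.0647 CPM) lay at the floor of rounded counts, so their SD and the size of the rise are uncertain. In the unfolded protein response 6 of 28 rose and 5 fell (CANX 1.33 and 0.82), and in the integrated stress response 9 of 31 rose and 12 fell (SLC38A2 1.55 and 0.42). Autophagy genes rose in 9 and fell in 14 of 40, p53 targets in 4 and 11 of 28, apoptosis regulators in 4 and 11 of 27, other redox enzymes in 4 and 9 of 24, and hypoxia genes in 7 and 6 of 22. Neurite genes rose in 5 and fell in 10 of 31 (DCX 1.25 and 0.48), ion channels in 7 and 9 of 25, neurotrophin genes in 4 and 6 of 20, ribosome biogenesis genes in 14 and 10 of 37, and metal response genes in 6 and 4 of 12. After removal of the GC trend no list in this paragraph so far had more than 2 members higher or 2 lower. Aryl hydrocarbon receptor targets had 4 tested members, 2 higher and 1 lower. Synaptic, ion channel, interferon, insulin signalling and hypoxia lists had a median and a mean, or a mean and a set test, of opposite sign.

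The G2/M list turned direction. With the deposited counts 14 of its 39 genes rose and 4 fell (ANLN 1.51), with a median of 0.337 and no call (adjusted p = 0.258). After removal of the GC trend 0 rose and 3 fell, ANLN stood at 0.52 without passing, and camera called the list lower (median -0.188, adjusted p = 0.0281). That call was lost without control 2, without Oligonol 2, with the longest transcript's GC and with an estimated correlation (adjusted p = 0.776).

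The tests on histone, ribosomal protein and respiratory chain genes, and that of chance on genes with the GC trend removed, were chosen after the results were seen. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 8112 changed genes and 1 as many as 882 with the GC trend removed, and the highest of the others gave 0 in both. Lists are another matter: 2 of the 10 splits gave as many as 6 called lists, with 6 the highest of the others, and 3 gave as many as 5 with the GC trend removed, with 8 the highest. These splits are too few for a share under 0.05.

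Protein-coding genes moved in both directions along GC content. Median transcript length is argued against as the cause, since rho with it was 0.090. With its trend removed 6361 protein-coding genes were called against 6393 before. Other measures of length are not excluded by this, and rho with the genomic span of the gene was 0.518. A technical difference in GC bias between the groups is a candidate explanation: rho with GC was -0.851, and calls among protein-coding genes went from 6393 to 516 with the trend removed. An axis of library quality is another, since the log ratio of Oligonol libraries 1 and 2, which had the same treatment, correlated at 0.794 across genes with the group difference computed from the other 4 libraries. That was the largest value. Oligonol 2 and 3 gave -0.754, Oligonol 1 and 3 0.254, and the control pairs 0.117, 0.377 and 0.319. The strong values thus both rest on Oligonol 2. An effect of Oligonol that follows GC content was not tested apart from these explanations and stays open.

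Histone, ribosomal protein and respiratory chain genes were lower also with the GC trend removed (camera adjusted p of 3.25e-13, 7.87e-11 and 2.04e-07 with the preset correlation, and 0.776, 0.895 and 0.776 with an estimated one, which called none of them). Their means then still differed between libraries by -1.012 (SE 0.244), -0.584 (SE 0.252) and -0.525 (SE 0.151). For the list medians, the part that went with the trend was -0.647 (95% bootstrap interval -0.912 to -0.044) for histones. It was -0.014 (-0.225 to 0.125) for ribosomal proteins and 0.134 (-0.151 to 0.419) for respiratory chain genes. These intervals are over list members and leave out the spread between libraries. Members also move together, with estimated correlations of 0.885, 0.623 and 0.293 in the planned fit. The differences between libraries argue against the GC trend as the whole cause for histones and respiratory chain genes, but not against a part in the fall of histones. For histones the argument is less sure, since the GC of members such as H3C8 came from transcripts longer than the deposited gene. The ribosomal protein means of the groups overlapped, so the argument is weak for that list and its fall is less sure in itself. A lower yield of short transcripts may contribute. Other protein-coding genes of like length had a median of -0.204 (95% bootstrap interval over genes, not libraries, -0.219 to -0.185). The lists stood at -0.633, and the spread between the other genes was 0.396. Fewer cells in S phase could lower histones, and the S phase list stood at -0.021 with a spread between genes of 0.321, which does not decide it. An Oligonol effect stays open, as the groups and any difference in library preparation coincide.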
